A study of Mus musculus with 8 samples.

How the data were processed

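Gene counts of 8 RNA-seq libraries from mouse haemogenic endothelium were analysed. Per the labels' protocols, the ES cells were grown and differentiated by an earlier published protocol, and 200 ng of total RNA per sample went into an Agilent strand-specific kit with 15 amplification cycles. The deposited table holds whole-number read counts per gene, not normalized, for 41128 genes and 8 libraries. Each of its 8 columns was matched to a sample by the sample's own description. Per the submitters' processing notes, the genome build was mm10, and bcl2fastq 2.17.1.14, Bowtie2 2.2.1, SAMtools 0.1.19, R 3.1.0 and edgeR 3.8.5 were used, with no role given. The counting program, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The kit marks strand, so whether the counting used it decides how reads of overlapping genes on opposite strands were assigned. Of 193 genes covered by the naming rule below, 23 overlap another tested gene, 21 of them on the opposite strand, and for 15 the overlapping gene has at least 0.1 times their CPM. Values of such genes, and of genes with near-identical copies, are uncertain. Of the gene identifiers in the table, 40254 were found in GENCODE M21 on GRCm38, 40245 of them on the same chromosome and 30616 with identical start and end.

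Groups came from the sample titles, which give the line, the agent and a replicate number. The counts of Hdac1 and Hdac2 could not check the labels, so groups are named as labelled. Genes were filtered with filterByExpr, which left 14179 genes holding 99.9% of counts, and libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3). A quasi-likelihood model with robust dispersion was fitted to all 8 libraries with a mean per group, so that the 4 groups share an estimate of the spread. Benjamini-Hochberg adjustment was applied at 0.05 within each comparison. The comparisons were 4OHT against EtOH in each line, the difference between these effects, and the EtOH libraries of the lines. Where a library was left out, the remaining library of its group was assumed to vary like the other groups. For a library of the Hdac2 line, these include both Hdac1 groups, which varied more. Calls lost there therefore do not show that a change rests on the library left out. Standard errors of log2 fold changes were taken from the F statistic. A ratio against a group with 1 to 3 counts carries an exact Poisson 95% interval. Such intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A floor of 3 counts corresponded to 0.15 to 0.287 CPM per library. The scripts were tested on counts simulated with a known set of changed genes. Sequence similarity was measured with BLAST 2.17.0 against the GENCODE M21 transcripts.

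The 25 gene lists, the naming rule and the comparisons were fixed before the data were examined. The lists were TGF-β pathway components, TGF-β-responsive genes, BMP pathway and targets, endothelial genes, arterial and Notch genes, blood transcription factors, blood surface and signalling genes, erythroid genes, megakaryocyte genes, macrophage and myeloid genes, smooth muscle and mesenchyme genes, and cardiomyocyte genes. The others were pluripotency genes, visceral endoderm genes, neuronal genes, DNA replication genes, mitosis genes, cyclin-dependent kinase inhibitors, p53 targets, HDAC1/2 complexes and class I HDACs, interferon-stimulated genes, cholesterol synthesis genes, oestrogen-responsive genes, immediate early and stress genes, and mitochondrially encoded genes. Lists were compared with the other genes by limma 3.58.1 camera with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance. List p-values were adjusted over all lists and comparisons together. Members called over all genes are counted beside members called when p-values were adjusted over the list alone. Some genes belong to several lists.

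The naming rule takes Hdac1 and Hdac2. It takes, for each 4OHT comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean CPM of at least 5 over the 8 libraries, whose 4OHT libraries both lie beyond both EtOH libraries, and whose symbol is not a predicted or clone name. It takes up to 4 members of each list with the smallest adjusted p in each 4OHT comparison. For the difference between the lines and for the EtOH libraries it takes the 5 highest and 5 lowest by the same filters, where for the difference every pairing of libraries had to set the lines apart. Gm10093, Grap2, Igf2r, the Y-linked genes and the genes that overlap named ones are named outside this rule, after their values were seen. The overlap of calls between the 4OHT comparisons was to be tested with Fisher's exact test per direction. With 0 calls in the Hdac1 line it could be run only at a threshold chosen after the data were seen, and there its p-values were not read as evidence. Counts were set against those of independent lists, and their fold changes were correlated across genes.

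Alternatives were DESeq2's size factors and upper quartile scaling, no filter and a filter at CPM above 1 in at least 2 libraries, DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom, edgeR's older quasi-likelihood method, fits of only the libraries compared, a replicate block, a 2-fold minimum, and leaving out each library. For a list, the 13 alternatives are the other scalings, the replicate block, each library left out, the estimated correlation and fry. A range of adjusted p over them mixes these tests and is not a spread of fry alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.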

Results

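RNA was sequenced from 8 samples of haemogenic endothelium, the specialised endothelium from which the earliest blood cells emerge. The cells were made by differentiating mouse embryonic stem (ES) cells of strain C57BL/6. They came from a line with lox sites at both copies of Hdac1 and a line with lox sites at both copies of Hdac2, which encode the class I histone deacetylases HDAC1 and HDAC2. Each line was labelled as treated with 4-hydroxytamoxifen (4OHT), a ligand widely used to switch on tamoxifen-dependent Cre recombinase, or with ethanol (EtOH), its solvent. Each of the 4 groups held 2 libraries. Total counts per library were 17125110 and 19552380 for Hdac1 lox/lox EtOH and 13127425 and 16730333 for Hdac1 lox/lox 4OHT. They were 15387579 and 10215792 for Hdac2 lox/lox EtOH and 13730921 and 12164178 for Hdac2 lox/lox 4OHT. Levels below are TMM-scaled CPM (counts scaled to library size), given as mean ± SD of the 2 libraries of a group unless a replicate is named. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14179 genes, fitted to all 8 libraries, and those of lists from camera. Genes that rose or fell passed this test at 0.05. No label says that the replicates were separate cultures, so p-values of genes measure only the spread between these samples, which may be technical. List p-values from camera compare a list's genes with other genes at a preset correlation between genes, not libraries with libraries. The correlations estimated from the data ran from -0.086 for pluripotency genes to 0.87 for mitochondrially encoded genes, and with them no list passed. A 4OHT-treated line without lox sites was not analysed here.

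The targeted genes were read in every library before the other genes. Hdac1 (chromosome 4, 129516104 to 129542713, mm10) stood at 5.69 ± 0.129 CPM in Hdac1 lox/lox EtOH and 7.05 ± 0.0922 CPM in the libraries labelled Hdac1 lox/lox 4OHT (log2 fold change 0.31 ± 0.23 SE, adjusted p = 0.84). In the Hdac2 lox/lox line Hdac1 stood at 7.31 ± 0.206 CPM with EtOH and 4.56 ± 0.794 CPM with 4OHT (log2 fold change -0.68 ± 0.24 SE, adjusted p = 0.056). That difference passed the threshold with upper quartile scaling, at -0.81, and with no scaling beyond library size, at -0.80. Hdac2 (chromosome 10, 36974544 to 37001889) stood at 158 ± 10.1 CPM in Hdac2 lox/lox EtOH and 149 ± 0.273 CPM in the libraries labelled Hdac2 lox/lox 4OHT (log2 fold change -0.08 ± 0.14 SE, adjusted p = 0.67). The 95% interval of its log2 fold change ran from -0.41 to 0.25. In the Hdac1 lox/lox line Hdac2 stood at 145 ± 4.11 CPM with EtOH and 146 ± 7.97 CPM with 4OHT. Gm10093 (chromosome 17, 78491565 to 78493541) is 99.38% identical to Hdac1 over 1444 bases, or 70.9% of the 2038-base Hdac1 transcript, and took more counts than Hdac1 itself. It stood at 136 ± 15.2 and 113 ± 3.06 CPM in the EtOH and 4OHT libraries of the Hdac1 line, and at 145 ± 15.2 and 109.8 ± 0.857 CPM in those of the Hdac2 line. The split of reads between Hdac1 and Gm10093 is therefore uncertain. The part of each gene between the lox sites is not given in the sources used here, and gene-level counts also take in exons outside it. These counts therefore do not check the labels, and EtOH and 4OHT below stand for what the libraries were labelled as.

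**Figure D1:**
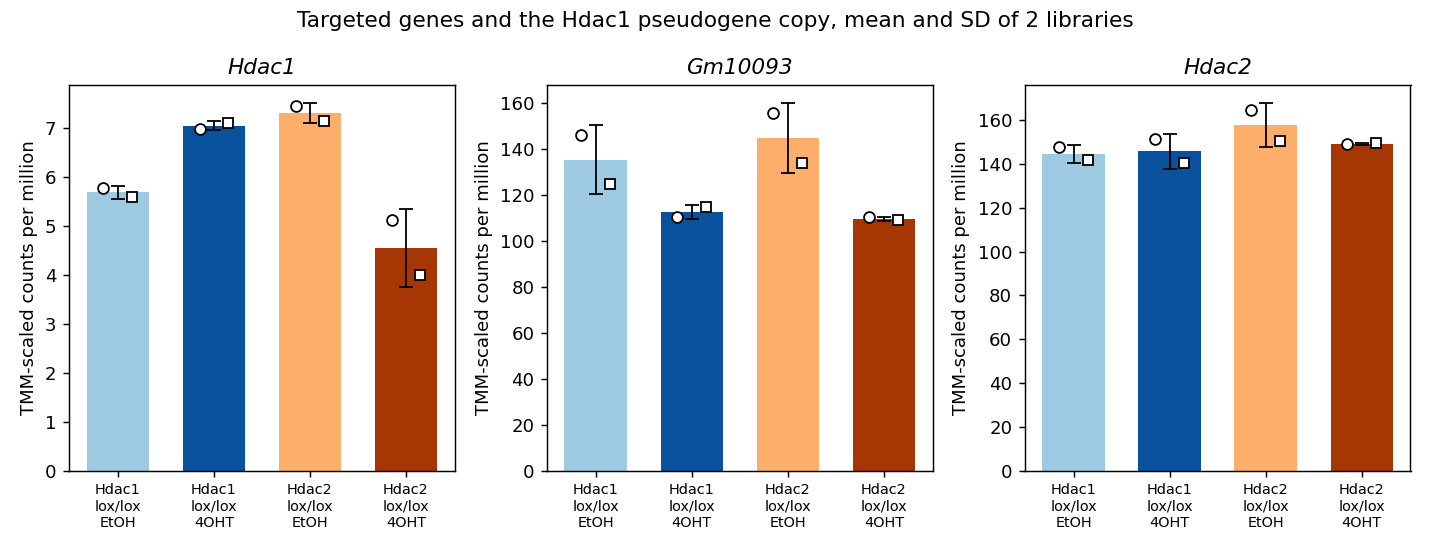
TMM-scaled CPM (linear axes from 0) of Hdac1, its near-identical copy Gm10093 and Hdac2 in the 4 labelled groups, with bars for means, error bars for SDs of 2 libraries, circles for replicate 1 and squares for replicate 2. Hdac2 lay between 140.3 and 165 CPM in all 8 libraries.

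In the Hdac2 lox/lox line, the comparison of 4OHT with EtOH asks what deletion of Hdac2 does to expression during the endothelial-to-haematopoietic transition. Edn1, the precursor of the vasoconstrictor endothelin-1, rose from 8.86 ± 7.27 to 485 ± 26.6 CPM (log2 fold change 5.74 ± 1.09 SE, adjusted p = 0.012) in the libraries labelled 4OHT. Met, the hepatocyte growth factor receptor gene, rose from 1.03 ± 0.169 to 40.1 ± 2.6 CPM (log2 fold change 5.30 ± 1.06 SE, adjusted p = 0.013). Gata1, a regulator of red cell and megakaryocyte formation, fell from 64.5 ± 7.63 to 6.39 ± 0.619 CPM (log2 fold change -3.33 ± 0.70 SE, adjusted p = 0.015). Klf1, the erythroid Krüppel-like factor gene, fell from 38.8 ± 16.6 to 2.36 ± 0.0504 CPM (log2 fold change -4.03 ± 0.95 SE, adjusted p = 0.019). Among other genes with the highest log2 fold changes, Igfbp7, which overlaps Polr2b, rose by 5.28 ± 1.11 SE, Npr3, the natriuretic peptide clearance receptor gene, by 5.62 ± 1.18, Lgr6 by 5.23 ± 1.30 and Slc35f1 by 6.60 ± 1.35. Sprr2b rose from 2 to 266 counts over the 2 libraries of each group, a depth-scaled ratio of 143 with a 95% counting interval from 39.1 to 1184. Slfn9 rose from 3 to 107 counts, a ratio of 38.3 with an interval from 12.7 to 188. Among genes with the lowest log2 fold changes, Fgf3 fell at -4.45 ± 0.96 SE, Cited4 at -3.55 ± 0.60, Trib3 at -3.45 ± 0.90, Reep6 at -3.38 ± 0.52 and Sla2, which overlaps another gene, at -3.41 ± 0.43. In all, 5113 of 14179 genes changed, 2680 higher and 2433 lower, and 3022 of them by at least 2-fold. DESeq2 called 5572 genes, edgeR's likelihood ratio test 5871 and limma-voom 4759. The count was 834 without 4OHT replicate 1, 88 without 4OHT replicate 2, 109 without EtOH replicate 1 and 0 without EtOH replicate 2, where 5041 genes had an unadjusted p under 0.05. EtOH replicate 2 also held more reads of the Y-linked gene Ddx3y than the other 3 libraries of the line (4.58 against at most 0.889 CPM), and whether it held other cells was not tested here. The log2 fold changes of the 16 highest and lowest genes ran from -4.65 to 7.24 without it, against -4.45 to 6.9996. Of the 16 genes that the naming rule took as highest or lowest here, 6, 1, 1 and 0 were still called in the same order, and 5 with no filter on low counts and 15 with limma-voom.

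Of the genes of TGF-β signalling, the pathway in the title of the series, more rose than fell in the libraries labelled 4OHT of the Hdac2 line. Of 27 pathway components tested, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Ltbp1, which holds latent TGF-β in the matrix, rose from 8.98 ± 0.954 to 73.9 ± 8.57 CPM (log2 fold change 3.04 ± 0.26 SE, adjusted p = 0.0041). Eng, a TGF-β co-receptor gene of endothelium that overlaps other genes, rose from 241 ± 16.5 to 891 ± 143 CPM (log2 fold change 1.88 ± 0.29 SE, adjusted p = 0.0087), and the receptor gene Tgfbr2 rose from 96.4 ± 20.8 to 257 ± 60.5 CPM (log2 fold change 1.42 ± 0.22 SE). Of 28 TGF-β-responsive genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone). The metalloproteinase inhibitor gene Timp3 rose from 215 ± 17.8 to 907 ± 80.3 CPM (log2 fold change 2.08 ± 0.19 SE, adjusted p = 0.0041), the fibrillar collagen gene Col3a1 rose from 6.46 ± 1.31 to 42.3 ± 13 CPM (log2 fold change 2.70 ± 0.35 SE, adjusted p = 0.0076), and the fibronectin gene Fn1 rose from 2618 ± 109.5 to 7597 ± 432 CPM (log2 fold change 1.54 ± 0.23 SE). The components list stood higher than other genes (adjusted p = 0.00056, and adjusted p = 0.75 with an estimated correlation), and so did the responsive list (adjusted p = 6.9e-05, and adjusted p = 0.75 with an estimated correlation). Both lists were drawn up because the series names the pathway, so they are not independent evidence of its direction. Of 30 endothelial genes, 15 rose and 2 fell (19 and 2 adjusted over the list alone). Cdh5, the endothelial cadherin gene, rose from 765 ± 29.2 to 2684 ± 484 CPM (log2 fold change 1.81 ± 0.31 SE, adjusted p = 0.0098), and Clec14a rose by a log2 fold change of 1.93 ± 0.26 SE. Tal1, a regulator of both endothelial and blood fate, fell from 335 ± 56.8 to 147 ± 7.54 CPM (log2 fold change -1.18 ± 0.18 SE, adjusted p = 0.0087). The endothelial list stood higher than other genes (adjusted p = 0.0016, and adjusted p = 0.75 with an estimated correlation). Of 14 arterial and Notch genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), and the list test did not pass (adjusted p = 0.089). The connexin gene Gja5 rose from 1.3 ± 0.0846 to 38.9 ± 28.5 CPM (log2 fold change 4.89 ± 0.61 SE, adjusted p = 0.0073), and the Notch ligand gene Jag1 rose from 3.7 ± 0.365 to 74.1 ± 10.2 CPM (log2 fold change 4.32 ± 0.84 SE, adjusted p = 0.013). Of 20 smooth muscle and mesenchyme genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone), and the list test did not pass (adjusted p = 0.082). Acta2, the smooth muscle actin gene and also 1 of 6 genes shared with the TGF-β-responsive list, rose from 1349 ± 248 to 3937 ± 1136 CPM (log2 fold change 1.55 ± 0.26 SE). Of 22 BMP pathway genes and targets, 5 rose and 3 fell (7 and 3 adjusted over the list alone), and the list test did not pass (adjusted p = 0.089). The receptor gene Acvr1 rose by a log2 fold change of 1.33 ± 0.25 SE and Bmp2 fell at -1.19 ± 0.25. Of the 63 genes called across these 6 lists, 21 were still called without 4OHT replicate 1, 5 without 4OHT replicate 2, 6 without EtOH replicate 1 and 0 without EtOH replicate 2, where 55 kept their direction at an unadjusted p under 0.05. The arterial list passed without EtOH replicate 2 (adjusted p = 0.041) and without 4OHT replicate 1 (adjusted p = 0.00897, with 0.009 to 0.75 over 13 alternatives). The mesenchyme list passed without 4OHT replicate 2 (adjusted p = 0.0303, with 0.03 to 0.75 over 13 alternatives). By fry, which does not compare a list with other genes, the components list (adjusted p = 0.058, with 0.00035 to 0.75 over 13 alternatives) and the endothelial list (adjusted p = 0.097, with 6.4e-05 to 0.75 over 13 alternatives) missed the threshold. The BMP list passed by camera in a fit of the Hdac2 line alone (adjusted p = 0.029, against 0.089 in the fit of all 8 libraries). The first value was adjusted over the lists of this comparison only, the second over all comparisons. It passed in none of the 13 alternatives that leave out at most 1 library.

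Blood genes of the Hdac2 line were read by lineage. Of 16 erythroid genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone), and the list stood lower than other genes (adjusted p = 0.00029, and adjusted p = 0.75 with an estimated correlation). Car2, the carbonic anhydrase 2 gene, fell from 287 ± 35.2 to 46.7 ± 0.835 CPM (log2 fold change -2.62 ± 0.21 SE, adjusted p = 0.0041). Epor, the erythropoietin receptor gene, fell from 33.6 ± 5.87 to 4.65 ± 0.211 CPM (log2 fold change -2.85 ± 0.51 SE, adjusted p = 0.011), and Tfrc, the transferrin receptor gene, fell from 222 ± 21.8 to 90.1 ± 25.7 CPM (log2 fold change -1.30 ± 0.21 SE). Of 20 blood transcription factors, 1 rose and 7 fell (2 and 8 adjusted over the list alone), and the list test did not pass (adjusted p = 0.16). Gfi1b, a repressor that helps blood cells to leave the endothelium, fell from 44 ± 3.55 to 6.77 ± 0.406 CPM (log2 fold change -2.70 ± 0.39 SE, adjusted p = 0.0087). Nfe2 fell at a log2 fold change of -3.02 ± 0.48 SE and Lmo2 at -2.01 ± 0.33, while Mecom, a regulator of stem cells, rose from 6.54 ± 3.85 to 93.2 ± 29.9 CPM (log2 fold change 3.86 ± 0.67 SE, adjusted p = 0.01). Runx1, the central regulator of this transition, had a log2 fold change of -0.35 ± 0.23 SE (adjusted p = 0.25). Of 11 megakaryocyte genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone), and the list test did not pass (adjusted p = 0.4). Itga2b, the gene of CD41, fell from 170.0 ± 25.8 to 45.4 ± 4.21 CPM (log2 fold change -1.91 ± 0.31 SE, adjusted p = 0.0089). Of 20 blood surface and signalling genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone), and the list test did not pass (adjusted p = 0.21). Lcp1, which encodes L-plastin, rose from 17.5 ± 0.415 to 96.2 ± 21 CPM (log2 fold change 2.46 ± 0.35 SE, adjusted p = 0.0085), and Ptprc, the gene of CD45, rose from 0.5 ± 0.302 to 3.56 ± 0.868 CPM (log2 fold change 2.74 ± 0.50 SE). Of 15 macrophage and myeloid genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone), and the list stood higher (adjusted p = 0.037, and adjusted p = 0.75 with an estimated correlation). Itgam, the gene of CD11b, rose from 0.696 ± 0.849 to 15.1 ± 0.508 CPM (log2 fold change 4.30 ± 0.76 SE, adjusted p = 0.011), while Mpo, the myeloperoxidase gene of granulocyte precursors, fell from 29.2 ± 4.42 to 3.91 ± 0.374 CPM (log2 fold change -2.90 ± 0.65 SE, adjusted p = 0.017). Of the 35 genes called across these 5 lists, 7 were still called without 4OHT replicate 1, 1 without 4OHT replicate 2, 2 without EtOH replicate 1 and 0 without EtOH replicate 2, where 32 kept their direction at an unadjusted p under 0.05. The myeloid list missed the threshold without 4OHT replicate 1 (adjusted p = 0.054) and without EtOH replicate 1 or 2 of the Hdac1 line, which share the fit (adjusted p = 0.0901 and 0.0686, with 0.0027 to 0.75 over 13 alternatives). It also missed it in a fit of the Hdac2 line alone (adjusted p = 0.093). By fry the myeloid (adjusted p = 0.097, with 0.0027 to 0.75 over 13 alternatives) and erythroid lists (adjusted p = 0.1, with 6.2e-05 to 0.75 over 13 alternatives) missed the threshold, and the blood transcription factors passed (adjusted p = 0.033, with 0.033 to 0.75 over 13 alternatives).

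Cell cycle genes of the Hdac2 line were mostly lower in the libraries labelled 4OHT. Of 25 DNA replication genes, 0 rose and 16 fell (0 and 19 adjusted over the list alone), and the list stood lower than other genes (adjusted p = 2.4e-05, and adjusted p = 0.75 with an estimated correlation). Gins1 fell from 24.5 ± 0.674 to 9.02 ± 1.57 CPM (log2 fold change -1.45 ± 0.20 SE, adjusted p = 0.0084) and Cdt1 fell from 138 ± 6.08 to 58.1 ± 4.4 CPM (log2 fold change -1.25 ± 0.22 SE, adjusted p = 0.01), and both act in the start of DNA replication. Of 24 mitosis genes, 3 rose and 11 fell (3 and 12 adjusted over the list alone), and the list test did not pass (adjusted p = 0.11). Ccnb1, the cyclin B1 gene, fell from 65.2 ± 4.72 to 30 ± 2.7 CPM (log2 fold change -1.12 ± 0.17 SE, adjusted p = 0.0087), while Mki67, which encodes the proliferation antigen Ki-67, rose from 101 ± 27.1 to 553 ± 235 CPM (log2 fold change 2.45 ± 0.39 SE, adjusted p = 0.0087). Of 17 interferon-stimulated genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone), and the list stood higher (adjusted p = 8.4e-05, and adjusted p = 0.55 with an estimated correlation). The RNA sensor gene Ddx58, which encodes RIG-I, rose from 3.82 ± 0.00295 to 28.8 ± 0.708 CPM (log2 fold change 2.91 ± 0.27 SE, adjusted p = 0.0041), and Parp14 rose from 1.81 ± 0.545 to 16.5 ± 4.92 CPM (log2 fold change 3.21 ± 0.38 SE, adjusted p = 0.0064). Of 23 cholesterol synthesis genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), and the list stood lower (adjusted p = 0.011, and adjusted p = 0.75 with an estimated correlation). Dhcr7, which encodes an enzyme of the last steps of this synthesis, fell from 317 ± 42.7 to 96.2 ± 21.7 CPM (log2 fold change -1.72 ± 0.47 SE, adjusted p = 0.027). Of 25 genes of HDAC1/2 complexes and other class I HDACs, 6 rose and 4 fell (6 and 4 adjusted over the list alone), and the list test did not pass (adjusted p = 0.63). The chromatin remodeller gene Chd4 rose from 354 ± 24.1 to 704 ± 12.1 CPM (log2 fold change 0.99 ± 0.18 SE, adjusted p = 0.01). Of 23 p53 targets, 0 rose and 3 fell (0 and 0 adjusted over the list alone), with 3 higher and 4 lower at an unadjusted p under 0.05 (list adjusted p = 0.97). Of 7 cyclin-dependent kinase inhibitors, 0 rose and 1 fell (0 and 1 adjusted over the list alone), and the member that fell was Cdkn2d, at a log2 fold change of -0.81 ± 0.18 SE. The test of that list did not pass (adjusted p = 0.86), and its median lay above 0 while its test direction was lower. Of the 61 genes called across these 7 lists, 11 were still called without 4OHT replicate 1, 2 without 4OHT replicate 2, 1 without EtOH replicate 1 and 0 without EtOH replicate 2, where 53 kept their direction at an unadjusted p under 0.05. The cholesterol list missed the threshold without 4OHT replicate 2 (adjusted p = 0.0658) and by fry (adjusted p = 0.3, with 0.0016 to 0.75 over 13 alternatives). The mitosis list passed without EtOH replicate 1 (adjusted p = 0.0353) and without 4OHT replicate 2 (adjusted p = 0.0496, with 0.035 to 0.75 over 13 alternatives).

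Another 7 lists hold markers of cell types that differentiating ES cells can also give, and of responses to the treatment itself, and none of these list tests passed in the Hdac2 line by camera. Of 17 cardiomyocyte genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with the list at adjusted p = 0.11. Hand2, a regulator of heart and mesenchyme, rose from 9.39 ± 3.47 to 103 ± 10.4 CPM (log2 fold change 3.47 ± 0.29 SE, adjusted p = 0.0041), and Tnni1, a troponin gene, fell from 18.4 ± 8.57 to 4.37 ± 0.52 CPM (log2 fold change -2.08 ± 0.37 SE). Of 16 immediate early and stress genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone), with the list at adjusted p = 0.37. Fos rose from 13 ± 1.07 to 72.9 ± 0.471 CPM (log2 fold change 2.49 ± 0.30 SE, adjusted p = 0.0069) and Egr1 rose from 20.6 ± 2.74 to 71.9 ± 20.8 CPM (log2 fold change 1.80 ± 0.24 SE). Of 9 oestrogen-responsive genes, read because 4OHT binds oestrogen receptors, 1 rose and 1 fell (1 and 1 adjusted over the list alone), with the list at adjusted p = 0.76. Cxcl12, a chemokine gene, rose from 15.1 ± 2.53 to 185 ± 37.8 CPM (log2 fold change 3.61 ± 0.33 SE, adjusted p = 0.0041) and Igfbp4 fell at a log2 fold change of -0.77 ± 0.20 SE. Of 10 neuronal genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with the list at adjusted p = 0.38. Nrcam rose from 0.582 ± 0.552 to 9.56 ± 1.08 CPM (log2 fold change 3.92 ± 0.54 SE, adjusted p = 0.0081) and Uchl1 rose by 1.42 ± 0.34 SE on the log2 scale. Of 6 pluripotency genes tested, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the list at adjusted p = 0.51, Tbx3 at 1.78 ± 0.26 SE, Dppa4 at -2.53 ± 0.49 and Sox2 at -1.61 ± 0.48. Of 4 visceral endoderm genes tested, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with the list at adjusted p = 0.11, Foxa2 at 3.35 ± 0.77 SE and Cubn at 1.24 ± 0.33. Of 7 mitochondrially encoded genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with 1 at an unadjusted p under 0.05 (list adjusted p = 0.89), and the list's median, mean and test differed in sign. Of the 19 genes called across these 7 lists, 9 were still called without 4OHT replicate 1, 2 without 4OHT replicate 2, 3 without EtOH replicate 1 and 0 without EtOH replicate 2, where 17 kept their direction at an unadjusted p under 0.05. By fry, which does not compare a list with other genes, the cardiomyocyte list passed (adjusted p = 0.0068, with 0.0068 to 0.75 over 13 alternatives). The visceral endoderm list passed without EtOH replicate 1 (adjusted p = 0.0499) and by fry (adjusted p = 0.048, with 0.048 to 0.75 over 13 alternatives).

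**Figure D2:**
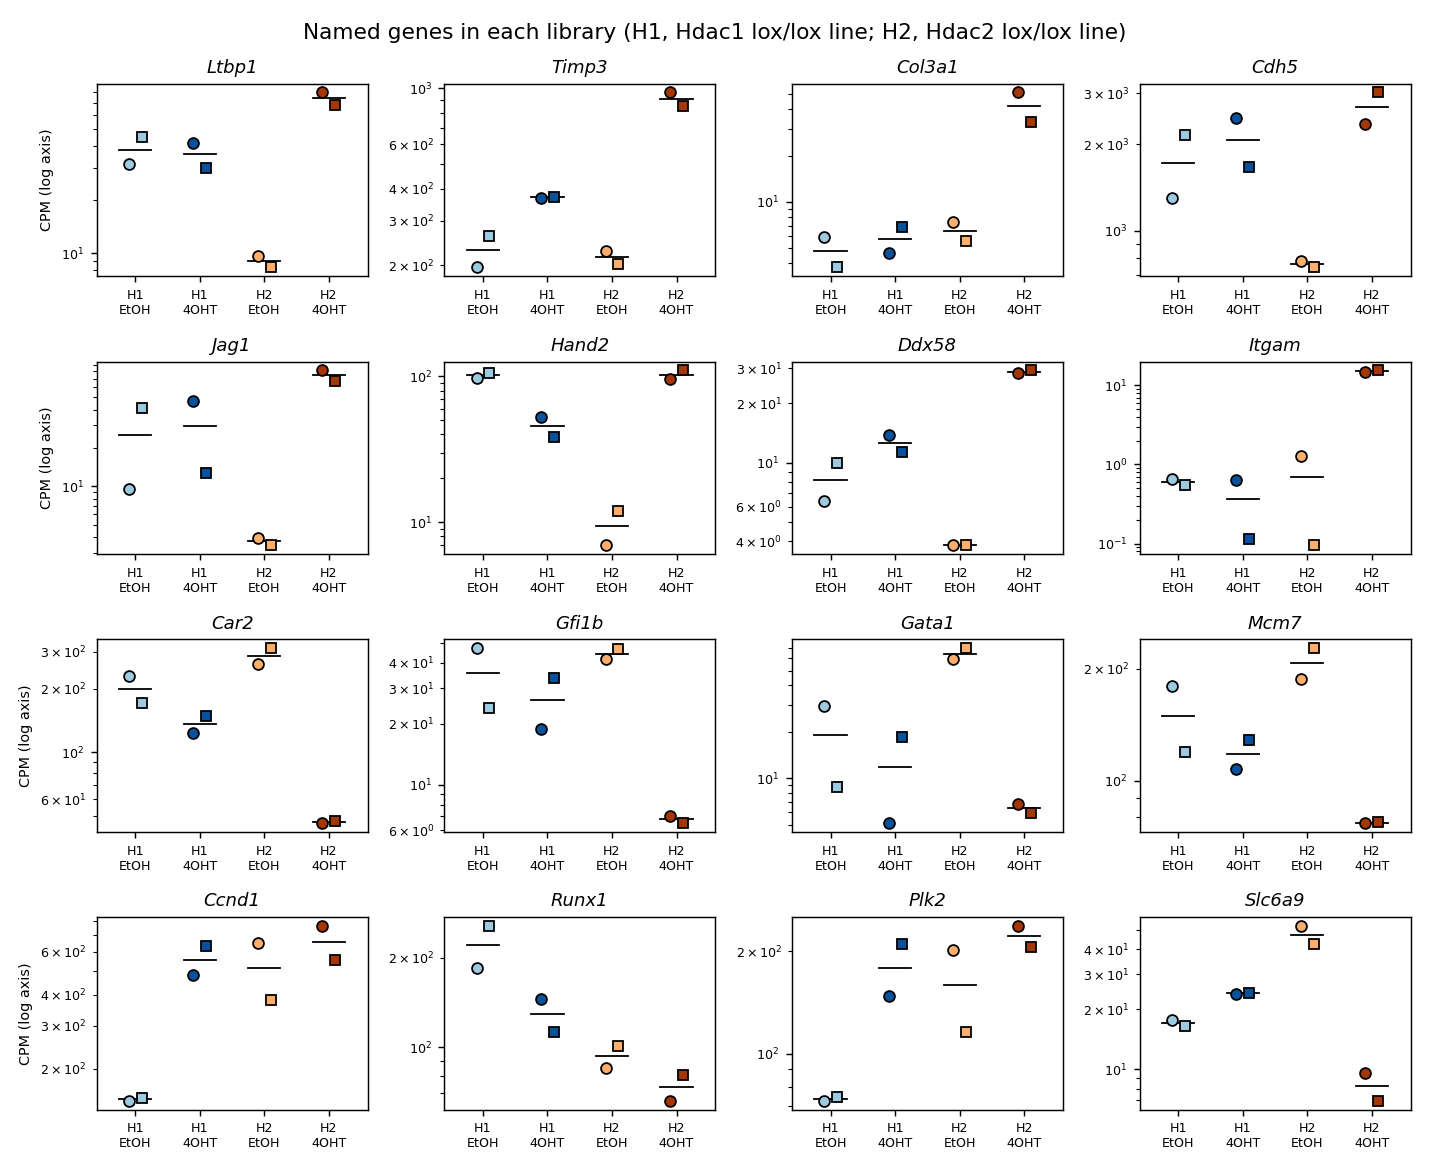
TMM-scaled CPM on log axes for 16 named genes in the 4 labelled groups, with circles for replicate 1, squares for replicate 2 and horizontal lines for means of 2 libraries. Ltbp1, Timp3, Col3a1, Cdh5, Jag1, Hand2, Ddx58 and Itgam are higher, and Car2, Gfi1b, Gata1 and Mcm7 (which overlaps other genes) lower, in both 4OHT libraries of the Hdac2 line than in both of its EtOH libraries.

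In the Hdac1 lox/lox line, the same comparison asks what deletion of Hdac1 does. As lists, and not as genes on their own, blood transcription factors and megakaryocyte genes lay lower and p53 targets and TGF-β-responsive genes higher in the libraries labelled 4OHT. Of 23 p53 targets, 22 had a positive log2 fold change (median 0.70), and the list stood higher than other genes (adjusted p = 9.5e-08, and adjusted p = 0.75 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 155 ± 38.4 CPM with EtOH and 331 ± 30.5 CPM with 4OHT (log2 fold change 1.10 ± 0.44 SE, adjusted p = 0.73). Plk2, a polo-like kinase gene, was at 73.5 ± 1.31 and 179 ± 43.6 CPM (log2 fold change 1.28 ± 0.28 SE, adjusted p = 0.71). Of 20 blood transcription factors, 2 had a positive log2 fold change (median -0.63), and the list stood lower (adjusted p = 6.2e-05, and adjusted p = 0.55 with an estimated correlation). Runx1 was at 220.4 ± 50.5 and 129 ± 23.5 CPM (log2 fold change -0.77 ± 0.23 SE, adjusted p = 0.71). Myb, needed for definitive blood, was at 52.6 ± 13.6 and 23.4 ± 7.89 CPM (log2 fold change -1.16 ± 0.30 SE, adjusted p = 0.71). Of 11 megakaryocyte genes, 0 had a positive log2 fold change (median -0.67), and the list stood lower (adjusted p = 6.9e-05, and adjusted p = 0.75 with an estimated correlation). Of 28 TGF-β-responsive genes, 25 had a positive log2 fold change (median 0.52), and the list stood higher (adjusted p = 5.8e-06, and adjusted p = 0.75 with an estimated correlation). Timp3 was at 229 ± 46.3 and 371 ± 3.84 CPM (log2 fold change 0.70 ± 0.19 SE, adjusted p = 0.71). The pathway was picked from the title, so that list is not independent evidence of its direction. Adjusted over the list alone, 4 blood transcription factors (Myb, Meis1, Lyl1, which overlaps another gene, and Runx1) and 2 megakaryocyte genes passed as lower and 1 p53 target as higher. For TGF-β-responsive genes that count was 0, with 3 at an unadjusted p under 0.05. These 4 lists kept their camera call at the preset correlation whichever library was left out. Their estimated correlations were 0.58 for p53 targets, 0.22 for megakaryocyte, 0.20 for TGF-β-responsive genes and -0.011 for blood transcription factors. By fry, which is 1 of the 13 alternatives, the blood transcription factors passed (adjusted p = 0.032). By the same test p53 targets (0.24), megakaryocyte (0.17) and TGF-β-responsive genes (0.17) did not.

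No gene passed edgeR's test over all genes in the Hdac1 line: the count was 0, with 947 genes at an unadjusted p under 0.05 (597 higher and 350 lower, against 709 by chance). In a fit of only the 4 libraries of this line, 595 genes had an unadjusted p under 0.05, fewer than the 709 by chance. The excess was therefore not seen with this line's own spread. DESeq2 called 32 genes, the likelihood ratio test 35 and limma-voom 0, where 989 had an unadjusted p under 0.05. The smallest adjusted p was 0.53, at Grap2. Ccnd1, the cyclin D1 gene, which overlaps another gene, was at 150.0 ± 3.02 CPM with EtOH and 557 ± 103 CPM with 4OHT (log2 fold change 1.89 ± 0.29 SE, adjusted p = 0.71). Erythroid (adjusted p = 0.00029), DNA replication (adjusted p = 0.027) and mitosis genes (adjusted p = 0.027) stood lower than other genes. Smooth muscle and mesenchyme (adjusted p = 0.006), immediate early and stress (adjusted p = 0.018), endothelial (adjusted p = 0.023) and oestrogen-responsive genes (adjusted p = 0.032) stood higher. All 7 calls were lost at adjusted p = 0.75 with an estimated correlation and at 0.18 to 0.53 by fry, and each was also lost without some library of this line (adjusted p in parentheses). Without EtOH replicate 1 this held for the endothelial (0.565), erythroid (0.422), mitosis (0.211) and oestrogen lists (0.082), and for the DNA replication list (0.689), which then stood higher. Without EtOH replicate 2 it held for the mesenchyme (0.515), mitosis (0.0547), oestrogen (0.0706) and immediate early lists (0.359). Without 4OHT replicate 1 it held for the endothelial (0.111), erythroid (0.169), DNA replication (0.182) and mitosis lists (0.0872). Without 4OHT replicate 2 it held for the mesenchyme (0.263), mitosis (0.109), oestrogen (0.181) and immediate early lists (0.553). Over 13 alternatives the highest adjusted p was 0.75 for each of the 7, and the lowest ran from 3.1e-06 for the erythroid list to 0.028 for the mitosis list. Adjusted over the list alone, 1 mesenchyme gene (Thy1, at 0.157 ± 0.00966 and 0.859 ± 0.0067 CPM) and 1 oestrogen-responsive gene (Ccnd1) passed as higher and 1 cardiomyocyte gene (Hand2) as lower. The remaining 14 lists were not called, with TGF-β pathway components at adjusted p = 0.082 and mitochondrially encoded genes at adjusted p = 0.078. The components list passed without EtOH replicate 2 (0.00115) or 4OHT replicate 2 (0.0124, with 0.0012 to 0.75 over 13 alternatives), and the BMP list without EtOH replicate 2 (0.00955, with 0.0095 to 0.81 over 13 alternatives). The cholesterol list passed without EtOH replicate 1 (0.000127) or 4OHT replicate 1 (0.00031, with 0.00013 to 0.86 over 13 alternatives), as did the mitochondrial list (0.00217 and 8.06e-05, with 8.1e-05 to 0.98 over 13 alternatives). Medians, means and tests differed in sign for arterial, blood surface, pluripotency and cyclin-dependent kinase inhibitor genes. In counts simulated for this comparison over 14179 genes, 0% of 67 genes changed by 1.5-fold were recovered, 16.4% of 67 changed by 2-fold and 84.8% of 66 changed by 4-fold. With the dispersion of the 4 Hdac1 lox/lox libraries in place of that of all 8, these shares were 0%, 2.99% and 69.7%. The simulated genes varied independently of one another, without the deviations that many genes shared in the Hdac1 line libraries. These shares therefore do not tell how many changes would be recovered in the real libraries.

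Libraries of the Hdac1 line differed within groups. The median absolute log2 difference between the 2 libraries of a group was 0.393 for Hdac1 lox/lox EtOH and 0.296 for Hdac1 lox/lox 4OHT, against 0.200 for Hdac2 lox/lox EtOH and 0.194 for Hdac2 lox/lox 4OHT. The median erythroid gene was 1.02 higher on the log2 scale in EtOH replicate 1 than in replicate 2, and 0.88 higher in 4OHT replicate 2 than in replicate 1. Gata1 was at 29.5 and 8.75 CPM in EtOH replicates 1 and 2 of the Hdac1 line and at 5.1 and 18.5 CPM in 4OHT replicates 1 and 2. Jag1 went the other way, at 9.5 and 41.2 CPM and at 46.8 and 12.6 CPM. Across genes, which are not independent replicates, the difference of EtOH replicate 1 from replicate 2 had a correlation of -0.65 with the 4OHT log2 fold change of the Hdac2 line. For the difference of 4OHT replicate 1 from replicate 2 it was 0.49.

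**Figure D3:**
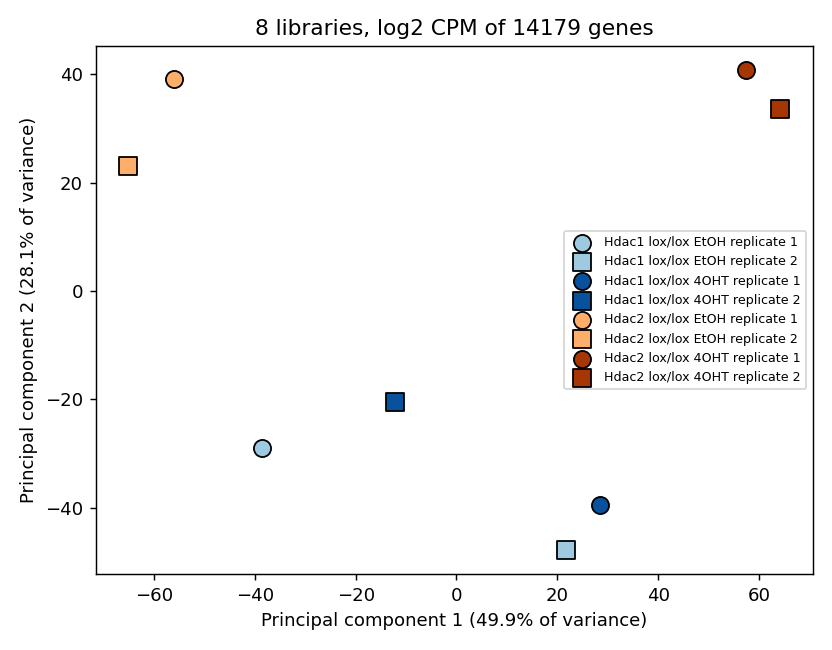
Principal components 1 and 2 (scores without unit) of log2 CPM of the 8 libraries, coloured by labelled group, with circles for replicate 1 and squares for replicate 2. Component 1 holds 49.9% of the variance and separates EtOH (-56.1 and -65.1) from 4OHT (57.4 and 64.1) in the Hdac2 line, while the Hdac1 EtOH libraries lie at -38.5 and 21.8 and the Hdac1 4OHT libraries at 28.5 and -12.1.

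The difference between the lines in their change with 4OHT was tested itself, since a call in a single line does not show that the lines differ. Hand2 rose in the Hdac2 line, while in the Hdac1 line it was at 102 ± 5.93 CPM with EtOH and 45.6 ± 9.75 CPM with 4OHT. The log2 change in the Hdac1 line minus that in the Hdac2 line was -4.63 ± 0.38 SE (adjusted p = 0.019). For Sprr2b, a small proline-rich protein gene, it was -6.82 ± 0.57 SE (adjusted p = 0.019), a fitted value that rests on 2 counts in the Hdac2 EtOH libraries. Car4, the carbonic anhydrase 4 gene, fell in the Hdac2 line from 32.6 ± 0.185 to 6.15 ± 1.4 CPM (log2 fold change -2.40 ± 0.21 SE) and was at 38.3 ± 1.88 and 51.3 ± 6.66 CPM in the Hdac1 line, a difference of 2.82 ± 0.28 SE (adjusted p = 0.034). Slc6a9, a glycine transporter gene that overlaps B4galt2, fell in the Hdac2 line from 47.2 ± 7.09 to 8.28 ± 1.9 CPM (log2 fold change -2.51 ± 0.22 SE) and was at 17.1 ± 0.795 and 24 ± 0.155 CPM in the Hdac1 line, a difference of 2.996 ± 0.30 SE (adjusted p = 0.034). These 4 genes, 2 in each direction, were all that passed, with 3973 at an unadjusted p under 0.05. DESeq2 called 1781, the likelihood ratio test 1927 and limma-voom 1. With no filter on low counts 1187 passed, and with no scaling beyond library size 11, of which 27.3% were higher. Leaving out Hdac1 EtOH replicate 1 gave 3773 calls, Hdac1 EtOH replicate 2 gave 12 and Hdac1 4OHT replicate 1 gave 3, with 2 of the 4 genes among them. No gene passed without Hdac1 4OHT replicate 2 or without any library of the Hdac2 line, where 2156 to 3033 genes had an unadjusted p under 0.05. Interferon-stimulated genes stood lower in this difference, so higher with 4OHT in the Hdac2 line than in the Hdac1 line (adjusted p = 2.4e-05, and adjusted p = 0.55 with an estimated correlation). DNA replication (adjusted p = 0.00024, and adjusted p = 0.75 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.0016, and adjusted p = 0.75 with an estimated correlation) stood higher in it. These 3 lists kept their camera call at the preset correlation whichever library was left out. Their estimated correlations were 0.029 for interferon-stimulated, 0.45 for DNA replication and 0.69 for cholesterol synthesis genes. By fry the interferon (adjusted p = 0.0087) and cardiomyocyte lists (adjusted p = 0.0087) passed, and the other 9 called here were at adjusted p = 0.16 to 0.43. A further 8 lists passed at adjusted p = 0.0078 to 0.043, each at adjusted p = 0.75 with an estimated correlation. TGF-β components, TGF-β-responsive, endothelial, arterial, cardiomyocyte and myeloid genes stood lower in the difference, and erythroid genes and p53 targets higher. Each lost its call without some library (adjusted p in parentheses). This held without Hdac1 EtOH replicate 1 for the myeloid (0.226), cardiomyocyte (0.0816) and p53 lists (0.237). Without Hdac1 EtOH replicate 2 it held for TGF-β components (0.0547), endothelial (0.0782), arterial (0.053) and erythroid genes (0.098). Without Hdac1 4OHT replicate 1 it held for the endothelial (0.0645), myeloid (0.064), cardiomyocyte (0.106) and p53 lists (0.0839), and without Hdac1 4OHT replicate 2 for the erythroid list (0.0536). Without Hdac2 EtOH replicate 1 it held for the arterial (0.0564), cardiomyocyte (0.0572) and p53 lists (0.148), and without Hdac2 EtOH replicate 2 for the TGF-β-responsive (0.119) and endothelial lists (0.077). Without Hdac2 4OHT replicate 1 it held for the TGF-β-responsive list (0.0652), and without Hdac2 4OHT replicate 2 for the endothelial (0.184), arterial (0.0804) and p53 lists (0.0766). Over the 8 libraries left out, adjusted p ran from 0.0016 to 0.055 for TGF-β components, 0.0006 to 0.12 for TGF-β-responsive, 0.0018 to 0.18 for endothelial and 0.002 to 0.08 for arterial genes. It ran from 0.003 to 0.098 for erythroid, 0.00041 to 0.23 for myeloid and 0.013 to 0.11 for cardiomyocyte genes and 4.6e-05 to 0.24 for p53 targets.

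Overlap between the lines was read because the series covers both deletions. With 0 genes called in the Hdac1 line by edgeR (947 at an unadjusted p under 0.05), 0 calls were shared. An unadjusted p under 0.01 in the Hdac1 line was therefore used as a threshold chosen after the data were seen. Of the 122 genes higher there, 44 rose in the Hdac2 line against 23.1 for independent lists, and 9 fell against 20.9. Of the 66 lower there, 26 fell in the Hdac2 line against 11.3, and 3 rose against 12.5. Fisher's exact test gave p = 7.0e-06 for the shared higher and, by the same exact test, p = 1.9e-05 for the shared lower genes. These p-values assume independent genes and are not read as evidence of a shared response, because the differences between replicates of the Hdac1 line were themselves correlated with the log2 fold change of the Hdac2 line, at -0.65 and 0.49. Genes shared as higher and as lower numbered 16 and 13 (against 14 and 10.9) without Hdac1 EtOH replicate 1, 351 and 169 (against 97.8 and 49.9) without Hdac1 EtOH replicate 2, 38 and 7 (against 21.7 and 3.36) without Hdac1 4OHT replicate 1 and 13 and 23 (against 6.15 and 6.51) without Hdac1 4OHT replicate 2. They numbered 14 and 6 without Hdac2 EtOH replicate 1, 0 and 0 without Hdac2 EtOH replicate 2, 17 and 5 without Hdac2 4OHT replicate 1 and 8 and 0 without Hdac2 4OHT replicate 2, where the Hdac2 line itself had 109, 0, 834 and 88 calls. Across 14179 genes the log2 fold changes of the lines, which share no library, had a Pearson correlation of 0.24 and a Spearman correlation of 0.28. Leaving out each library in turn moved the Pearson value between -0.18 and 0.55, with a jackknife SD over libraries of 0.61, so its size and sign rest on single libraries.

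Between the EtOH libraries of the lines, H19, an imprinted non-coding RNA gene, was higher in the Hdac1 line, at 1644 ± 151 against 20.9 ± 15.2 CPM (log2 fold change 6.31 ± 0.55 SE, adjusted p = 0.0056). Pdlim3, a muscle Z-line protein gene, was higher at 33.1 ± 27.3 against 1.21 ± 0.492 CPM (log2 fold change 4.72 ± 1.00 SE, adjusted p = 0.034), as were Gpm6a, Slfn9 and Sprr2b. Cdx2, a caudal homeobox gene, was lower in the Hdac1 line, at 1.26 ± 1.22 against 15.5 ± 4.81 CPM (log2 fold change -3.63 ± 0.87 SE, adjusted p = 0.044). Nr4a1, an orphan nuclear receptor gene, was lower at 8.6 ± 0.567 against 67.1 ± 8.59 CPM (log2 fold change -2.96 ± 0.58 SE, adjusted p = 0.031), as were Tmem119, Pcdh19 and Mogat2. In all, 1323 genes differed, 911 higher (68.9%) and 412 lower in the Hdac1 line. Without scaling beyond library size, 79.8% of 1557 calls were higher. DESeq2 called 2801 genes, the likelihood ratio test 2937 and a fit of the 4 EtOH libraries alone 154, and 2064 passed with no filter on low counts. The count was 3896 without Hdac1 EtOH replicate 1 and 172 without Hdac1 EtOH replicate 2. It was 1 and 4 without Hdac2 EtOH replicates 1 and 2, and 171 and 168 without Hdac2 4OHT replicates 1 and 2, which share the fit. Of the 10 genes named here, 10, 4, 1, 1, 4 and 4 were still called in that order, 5 with no filter and 8 each with limma-voom and with the 4 EtOH libraries alone. Cholesterol synthesis genes (adjusted p = 2.2e-05, and adjusted p = 0.75 with an estimated correlation), erythroid genes (adjusted p = 6.4e-05, and adjusted p = 0.75 with an estimated correlation) and p53 targets (adjusted p = 0.0062, and adjusted p = 0.75 with an estimated correlation) stood lower in the Hdac1 line. Neuronal genes stood higher (adjusted p = 0.04, and adjusted p = 0.75 with an estimated correlation). By fry these 4 lists were at adjusted p = 0.061 to 0.32 and none passed. The p53 list missed the threshold without EtOH replicate 1 of the Hdac1 line (adjusted p = 0.211) or of the Hdac2 line (0.122), with 2.1e-05 to 0.21 over the 8 libraries left out. The neuronal list missed it without Hdac1 EtOH replicate 1 (adjusted p = 0.0932) or Hdac2 EtOH replicate 2 (0.0907), with 0.0064 to 0.093 over the 8.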

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

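The tests of spread between replicates, size of response, exchanged labels and erythroid share in this part were chosen only after the results they bear on were seen, and the depth tests before. The log2 change with 4OHT differed between the lines, by a test of the difference itself, for Sprr2b at -6.82, Hand2 at -4.63, Slc6a9 at 2.996 and Car4 at 2.82, each given as the Hdac1 line minus the Hdac2 line. All 4 lost their call without any library of the Hdac2 line or without Hdac1 4OHT replicate 2, and 2 of the 4 without Hdac1 4OHT replicate 1. Sprr2b rests on 2 counts in the Hdac2 EtOH libraries.

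The Hdac2 line had 5113 called genes with 4OHT and the Hdac1 line 0 by edgeR (947 at an unadjusted p under 0.05; 32 with DESeq2). The tables argue against depth, since with every library thinned to the total of the shallowest the Hdac2 line still had 5030 calls and the Hdac1 line 0. The spread between replicates was larger in the Hdac1 line. The common dispersion of its 4 libraries was 3.55 times that of the Hdac2 line (0.0692 against 0.0195). In the fit of all 8 libraries the groups share an estimate of the spread, so it bears on both lines alike. It therefore does not account for the 5113 against 0 calls of that fit. It may add to the contrast in fits of each line's own 4 libraries, with 0 calls in the Hdac1 line and 7272 in the Hdac2 line. A smaller response in the Hdac1 line may hold. Its response SD, from differences that share no library, was 0.341 ± 0.0055 of that in the Hdac2 line. The SE is over chromosomes, which covers genes and not libraries. That value pairs the Hdac1 libraries by crossed numbers. Paired by the same number, their covariance was not positive and was set to 0, so that pairing gave no estimate. The smaller response stays open as a hypothesis, with 2 libraries per group, and so does the larger spread for the fits of each line alone.

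The libraries of each Hdac1 group differed in opposite directions for the same replicate number, with a correlation of deviations across genes of -0.69. The tables argue against depth, as that correlation was -0.64 after thinning. An exchange of labels between the replicate 2 libraries cannot be told apart from a difference between cultures: of the 3 splits of the 4 libraries into pairs, the labelled split gave 0 calls, the split that exchanges these labels 1984 and the other split 0, which points to a structure of these samples that either would give. The other columns for these splits go both ways, with 11, 7 and 2 lists called and a correlation of 0.24, 0.60 and 0.23 with the log2 fold changes of the Hdac2 line, in the order labelled, exchanged and other. A different share of erythroid cells cannot be told apart either. The median erythroid gene differed by 1.02 and 0.88 in the needed directions. The correlation was still -0.45 over 5690 genes that do not follow the erythroid mean, by a bound of 0.5 set after the data were seen. Whether a gene followed that mean was read over all 8 libraries, where the lines also differ. Some of these genes may still follow it within the Hdac1 line, so the -0.45 does not count against a different erythroid share.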

How the results depend on the processing

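No scaling, the newer quasi-likelihood method, the crossed block, the block across lines, the unadjusted threshold for overlap and the list counts of the Hdac2 line alone were chosen after seeing the data. The older quasi-likelihood method is the default of the installed edgeR, so it equals the reported result by construction. No called gene named by the rule changed direction under any alternative run. For the Hdac1 line, calls were 0 with every scaling, the CPM filter, limma-voom, the newer method, the line's own 4 libraries and each library left out (697 to 2438 at an unadjusted p under 0.05 without a library), against 4 with no filter, 32 with DESeq2 and 35 with the likelihood ratio test. For the Hdac2 line, calls were 4759 to 5871 over scalings, filters and tools, 7272 from its own 4 libraries (with 5099 of the 5113 kept), 3022 with a 2-fold minimum and 0 to 6434 with 1 library left out. For the difference, calls were 11 without scaling, 1187 with no filter, 1781 with DESeq2, 1927 with the likelihood ratio test, 1 with limma-voom and 0 to 3773 with 1 library left out. For the EtOH libraries, calls were 2064 with no filter, 2801 with DESeq2, 2937 with the likelihood ratio test, 154 from the 4 libraries alone, 853 with a 2-fold minimum and 1 to 3896 with 1 library left out. Fewer samples leave fewer degrees of freedom, which alone would not give the rise to 7272 calls from the Hdac2 line's own 4 libraries. The estimate of spread in a fit also changes with the libraries it holds. The common dispersion was 0.0692 in the Hdac1 line and 0.0195 in the Hdac2 line. Otherwise the cause was not tested. A fit of only the compared libraries was not run for the difference, which needs all 8. Upper quartile scaling moved the median gene of the Hdac2 line to -0.15 and no scaling to -0.14, with 43.5% and 44.3% of calls higher against 52.4%, so the split between directions is relative to that shift. Hdac1 in the Hdac2 line passed the threshold at -0.81 and -0.80 under these scalings. Shared calls between the lines were 0 with DESeq2's size factors, the replicate block, each library left out, an adjusted p under 0.10 and a 2-fold minimum, against 70 at the unadjusted threshold, and were not counted for the other tools and filters. Lists called in the Hdac1 line, the Hdac2 line, the difference and the EtOH libraries numbered 11, 8, 11 and 4, and 0 in each with an estimated correlation. By fry 1, 6, 2 and 3 lists passed, of which 1, 3, 2 and 0 were among those called by camera. In a fit of the Hdac2 line alone, with adjustment over the lists of that comparison only, 8 lists passed. There the myeloid list lost its camera call (adjusted p = 0.093 against 0.037) and the BMP list gained it (0.029 against 0.089). With 1 library left out the lists called numbered 7 to 12 for the difference and 3 to 7 for the EtOH libraries. DNA replication genes reversed in the Hdac1 line without EtOH replicate 1, where their direction went from -1 (lower) to 1 (higher) at adjusted p = 0.69 (0.00029 to 0.75 over 13 alternatives). Low counts limit genes near the floor such as Sprr2b. They also limit Hdac1 itself, at group means of 4.56 to 7.31 CPM, where the split of reads with Gm10093 is uncertain.

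With the replicate number as a block, calls were 0 in the Hdac1 line (555 at an unadjusted p under 0.05), 0 in the Hdac2 line (5235) and 0 for the difference (2187). With a replicate block on the same number in both lines, calls were 449 for the EtOH libraries against 1323 (341 of the 449 higher, with 4060 at an unadjusted p under 0.05), and same-numbered EtOH libraries of the lines had deviations correlated at -0.04. Same-numbered EtOH and 4OHT libraries had deviations correlated at -0.69 in the Hdac1 line and 0.26 in the Hdac2 line, and 2 pairs per line do not show that numbers pair the samples. Pairing crossed numbers in the Hdac1 line gave 858 calls there, 8574 in the Hdac2 line and 5852 for the difference.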

Other observations

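The tests of gene clusters and of extra chromosome copies in this part were chosen only after the chromosome medians were seen, and the GC test before. Further genes covered by the naming rule also moved in the Hdac2 line with 4OHT. Ltbp3, a latent TGF-β binding protein gene that overlaps another gene, rose from 2.12 ± 0.0268 to 8.72 ± 1.27 CPM (log2 fold change 2.04 ± 0.35 SE, adjusted p = 0.0099). Col4a2, a basement membrane collagen gene that overlaps Col4a1, rose from 619 ± 98.4 to 3834 ± 309 CPM (log2 fold change 2.63 ± 0.41 SE, adjusted p = 0.0087), and the receptor gene Notch4 rose from 34.8 ± 6.64 to 181 ± 60.8 CPM (log2 fold change 2.38 ± 0.49 SE, adjusted p = 0.014). Mcm7, a subunit gene of the replicative helicase that overlaps other genes, fell from 208 ± 27.6 to 77.2 ± 0.36 CPM (log2 fold change -1.43 ± 0.23 SE, adjusted p = 0.0087). Aurkb, a mitotic kinase gene, fell from 113 ± 12.4 to 53.3 ± 1.75 CPM (log2 fold change -1.08 ± 0.18 SE, adjusted p = 0.0089), while Cenpe, a kinetochore motor gene, rose from 30.8 ± 1.18 to 140.4 ± 30 CPM (log2 fold change 2.19 ± 0.27 SE, adjusted p = 0.0069). The call of each of these genes was lost without Hdac2 EtOH replicate 2, where 0 genes passed edgeR's test and 5041 had an unadjusted p under 0.05.

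Y-linked genes were read in every library after the data were seen. Ddx3y was at 25.8, 45.7, 44.8 and 29.5 CPM in the Hdac1 line (EtOH replicates 1 and 2, then 4OHT replicates 1 and 2) and at 0.324, 4.58, 0.466 and 0.889 CPM in the Hdac2 line in the same order. Uty was at 0.519, 5.63, 0.233 and 0.355 CPM in the Hdac2 line, and Eif2s3y at 0.324, 5.63, 0.31 and 0.089 CPM. H19 was at 10.1, 31.6, 12 and 12.7 CPM in those 4 libraries. Hdac2 EtOH replicate 2 held the highest value of the 4 for each of these genes. In the EtOH libraries of the Hdac1 line H19 was at 1537 and 1751 CPM. Igf2r, at 262 and 378 CPM in the EtOH libraries of the Hdac1 line, did not set that library apart. It was at 33.1 and 34.1 CPM in Hdac2 EtOH replicates 1 and 2. Whether Hdac2 EtOH replicate 2 held other cells was not tested here. Without it the log2 fold changes of the 16 highest and lowest genes of the Hdac2 line ran from -4.65 to 7.24, against -4.45 to 6.9996 with it. These 16 genes were picked as extremes with that library included, so the range does not show whether other changes kept their size. Calls of the line fell without any 1 of its 4 libraries. In such fits the spread comes from the groups that still hold 2 libraries, among them both Hdac1 groups. The common dispersion was 0.0692 in the Hdac1 line and 0.0195 in the Hdac2 line. The loss of calls therefore does not show that the changes of the line rest on Hdac2 EtOH replicate 2.

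Between the EtOH libraries, genes on chromosomes 8, 11, 14 and 16 were higher in the Hdac1 line than in the Hdac2 line, with median log2 differences of 0.37, 0.33, 0.44 and 0.26, against at most 0.034 on any other autosome. The tables argue against GC content, since the lowest of the 4 medians was 0.248 after the GC trend was removed, against 0.082 on the highest other autosome. With each chromosome divided by position into 4 parts of equal gene number, they argue against a few changed gene clusters on chromosomes 8 and 11, where the lowest part was at 0.259 against 0.174 in the highest part of any other autosome, while clusters cannot be told apart from wider changes for 14, where the lowest part was at 0.0024, or for 16, where it was at 0.1497, just under that bound. Extra copies in part or all of the cells of the Hdac1 line may account for chromosomes 8, 11 and 16 as a hypothesis. Between the 4OHT libraries every part was above the highest part of any other autosome (lowest 0.233 against 0.172). Between the EtOH libraries this did not hold for 16. No whole-chromosome median exceeded 0.469, below the 0.585 of 3 copies against 2. These medians are relative to the scaling. The medians of the other autosomes ran from -0.149 to 0.104 between the 4OHT libraries, most of them below 0. The gap to 0.585 therefore does not show that only part of the cells held extra copies. A comparison of the lines also does not tell which line differs in copy number. The tables argue against a whole extra chromosome 14, since its part from 7293648 to 31668579 was at -0.198 between the 4OHT libraries, and no DNA data were used here.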
